A study of Mus musculus with 18 samples.

How the data were processed

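RNA-seq was carried out on LT-HSC sorted from mouse bone marrow into 96-well plates, as 18 libraries in 6 groups of 3. Per the labels, complementary DNA was made with a SMARTer ultra low input kit and libraries with Nextera chemistry, which keeps no strand information. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.10 and Cufflinks with the mm10 assembly. The authors deposited 1 table of 44349 Ensembl genes with 1 column per library. The deposited values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library, which the header does not name as a unit and which was checked on the values. The annotation release and the handling of replicates are not stated.

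Symbols and positions came from GENCODE M21 on GRCm38, the same assembly as mm10. It matched 43938 identifiers, and the symbol of the deposited table was used for the other 411. Missing values occurred in 33 cells of 16 genes, Trp53 among them, and these genes were left out. No column was left out.

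Values were analysed as log2(FPKM + 1) for the 14285 genes with at least 1 FPKM in at least 3 of the 18 libraries. A model with 1 mean per group was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend and robust variance moderation. Contrasts between pairs of groups were: knockout with wild type in each set, Wnt5a with its control in each genotype, KO Wnt5a with WT, and WT Reserve with WT. The other contrasts were interactions, of Wnt5a with genotype and of genotype with the reserve label. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 within a contrast. No replicate block was used, since no label says that equal numbers mark a shared animal or day. Summaries and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

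The 34 gene lists were fixed from general knowledge of stem cells, Wnt and retinoic acid signalling and of the blood lineages that a sort could hold. Of their 964 entries 953 matched a gene in the table, for 926 distinct genes. The 33 lists with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01 and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists of a comparison. Counts of called genes are given over all genes and adjusted over the list alone.

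Genes were named by a rule: the measured Hoxb genes, Wnt5a and the genes of the sort gate; per comparison the 10 genes that rose and the 10 that fell most among called genes whose groups did not overlap, with at least 5 FPKM in the higher group, without unnamed models and pseudogenes; and up to 4 genes with the smallest p of each list that passed or held several called genes. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were eligible. Wnt5a and Itga2, which encodes CD49b, were below the filter. The design, lists, rule and the first set of alternatives were fixed before the data were examined.

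The deposited table holds no counts. Depth was inferred from 8625 genes with a single transcript of moderate length, taking the lowest frequent value of a library as 1 fragment. It came to 19800000 to 40300000 fragments per library, at which 1 fragment on a transcript of 1 kb is 0.0248 to 0.0506 FPKM. Such floors cover counting error only, and amplified fragments are not independent molecules. The mitochondrial transfer RNA gene mt-Ts1, a very short transcript, made up 32.0% to 71.3% of the sum of FPKM in a library, so sums of FPKM were not used for scaling. Pearson correlations between replicates on the log2 scale ran from 0.932 to 0.968.

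Alternatives to the main choices were quantile normalization, median-ratio scaling, a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, limma without trend and robust moderation, library weights, only the libraries of a comparison, replicate number as a block, a minimum change of 1 on the log2 scale, and leaving out each library in turn. Chosen after the data were seen were 11507 nuclear coding genes of at least 300 bp, only the 12 libraries without the reserve label, and removal of a trend along transcript length. Other splits of the same libraries were counted, all 10 for each pair of groups and 100 drawn for each interaction. Correlations between comparisons that share libraries were set against simulations of noise without effects. Standard errors of list medians came from 1000 bootstrap resamples of genes. The model was tested on simulated data with 200 changed genes in 14285, where it called 80% to 89% of genes with a 2-fold change and 96% to 97% of genes with a 4-fold change, with 3 to 15 false calls. The changed genes were drawn from those above 2 on the log2(FPKM + 1) scale in the reference group, so these shares do not cover genes of lower level. Another 30 genes, shifted by 0.5 as a list, were not counted as false calls.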

Results

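Gene expression was measured by RNA-seq in long-term haematopoietic stem cells (LT-HSC) sorted from the bone marrow of wild-type mice and of mice lacking DERARE, a distal retinoic acid response element of the Hoxb gene cluster. The 18 libraries form 6 groups of 3. Wild-type cells (WT), wild-type cells with the Wnt5a label (Wnt5a), knockout control cells (KO Ctrl) and knockout cells with the Wnt5a label (KO Wnt5a), described as a rescue of the knockout, make up 12 libraries. The reserve LT-HSC, gated as CD49b-low, make up the other 6 libraries, from wild-type (WT Reserve) and knockout mice (KO Reserve). Wnt5a is a ligand of noncanonical Wnt signalling, and the labels do not say how or for how long it was given.

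The deposited FPKM of 14285 genes passed the filter on low values. The smallest steps between values imply 19800000 to 40300000 fragments per library, so that 3 fragments on a transcript of 1 kb correspond to 0.075 to 0.152 FPKM. KO Ctrl replicate 1 had the lowest implied depth outside the reserve set, at 21400000 fragments. The reserve libraries separated from the other 12 on the first principal component, which held 53.28% of the variance. Levels below are mean FPKM ± SD with n = 3 libraries per group, and log2 fold changes carry their SE from limma. The labels do not say whether replicates came from separate animals, so p-values measure the spread between libraries only.

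DERARE is an element and not a gene, so its loss cannot be read from the expression table, and the Hoxb genes near it were examined before all others. Of 12 listed Hoxb genes and transcripts, 3 passed the filter. Hoxb2 (ENSMUSG00000075588, chromosome 11, 96350525 to 96354012 in GRCm38) stood at 3.29 ± 0.164 in WT, 4.23 ± 0.895 in KO Ctrl, 1.75 ± 0.522 in WT Reserve and 1.19 ± 0.442 in KO Reserve, with adjusted p = 0.502 and 0.17 for the genotype differences. Hoxb4, below the filter, was at 0.334 ± 0.0936 in WT Reserve and 0.298 ± 0.0584 in KO Reserve, and Hoxb5 at 0.754 ± 0.207 and 0.186 ± 0.0717. The antisense transcript Hoxb5os (96291024 to 96306910), which spans Hoxb5 and Hoxb6 and cannot be told from them by strand in these unstranded libraries, had lower values in KO Reserve (log2 fold change -0.72, SE 0.20, adjusted p = 0.00914), a call that ended without WT Reserve replicate 1 (-0.47, adjusted p = 0.0561) and when only these 6 libraries were fitted (adjusted p = 0.0665). The median log2 fold change of the measured Hoxb genes was -0.34 for KO Reserve against WT Reserve (adjusted p = 0.631), 0.27 for KO Ctrl against WT (0.143), 0.26 for Wnt5a against WT (0.308) and 0.29 for KO Wnt5a against KO Ctrl (0.714). In KO Reserve it was -0.12 with quantile normalization, -0.19 with median-ratio scaling and -0.05 with the length trend removed. Without KO Ctrl replicate 1 the median was 0.55 for KO Ctrl against WT and 0.01 for KO Wnt5a against KO Ctrl. Without a filter on low values the Hoxb list passed camera in both of these comparisons.

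KO Reserve against WT Reserve addresses what differs in the reserve libraries of mice without DERARE. These libraries also held transcripts of other cells. The granulocyte transcripts S100a8, S100a9, Ltf, Ngp and Camp summed to 6350 ± 3260 FPKM in WT Reserve and 2650 ± 563 in KO Reserve, against 1.94 ± 1.33 in WT. A change in the makeup of cells can therefore not be told from a change within LT-HSC. Genes that mark LT-HSC were lower in the knockout. Procr, which encodes the endothelial protein C receptor used to purify LT-HSC (ENSMUSG00000027611, chromosome 2, 155751117 to 155755471), was at 1.42 ± 0.231 in KO Reserve and 17.5 ± 3.17 in WT Reserve (log2 fold change -2.92, SE 0.21, adjusted p = 6.15e-08). Ndn, a growth suppressor expressed in quiescent stem cells, fell by 2.82 on the log2 scale (SE 0.16), and the stem cell transcription factors Hlf and Meis1 fell by 2.21 (SE 0.15) and 1.92 (SE 0.11). Erythroid genes moved the other way: Ank1, the ankyrin of the red cell membrane skeleton, rose from 2.47 ± 0.594 to 9.62 ± 2.78 (log2 fold change 1.59, SE 0.18). A pair of transcripts outside the gene lists differed as well: the X-linked RNA Xist stood at 0.334 ± 0.414 in WT Reserve and 7.40 ± 2.09 in KO Reserve, and AA465934 at 19.3 ± 3.15 and 1208 ± 221, where WT had 174 ± 16.2 and KO Ctrl 3.29 ± 1.13.

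**Figure D1:**
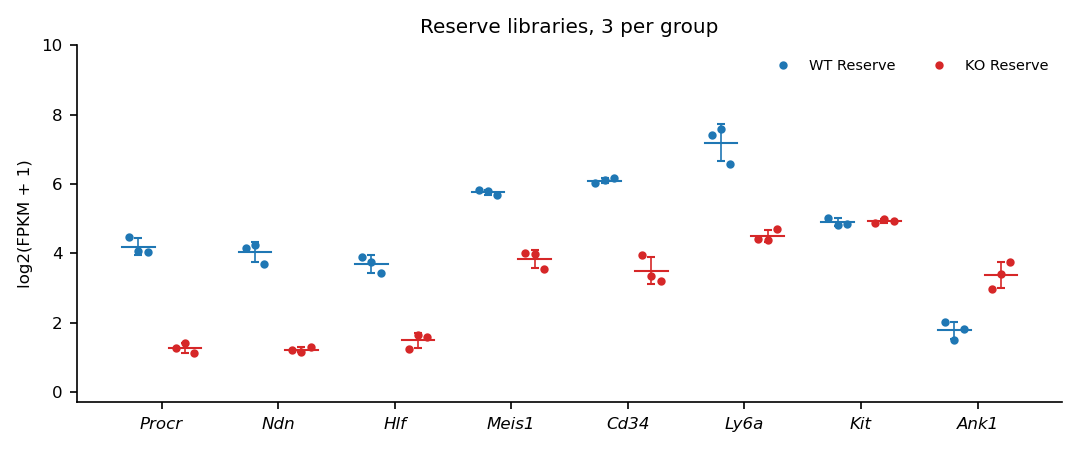
Expression of 8 genes in the reserve libraries, as log2(FPKM + 1) on the vertical axis; each point is 1 library, horizontal lines are group means and bars are SD over the 3 libraries of WT Reserve (blue) and KO Reserve (red). All but Kit and Ank1 lie lower in every KO Reserve library than in any WT Reserve library, and Ank1 lies higher.

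In all, 1708 genes rose and 4191 fell in KO Reserve. The median of all genes was itself shifted by -0.17, and with quantile normalization the split was 3154 higher and 2764 lower around a median of 0.03, so changes are best read against that shift. Of 33 tested gene lists, 21 passed camera, and 5 of these held when the correlation between genes was estimated from the data: LT-HSC genes, multipotent progenitor genes, quiescence genes, erythroid genes and interferon response genes. Of 38 LT-HSC genes 30 fell and 2 rose (31 and 3 adjusted over the list alone), with a median of -1.05 and adjusted p = 0.0109 with an estimated correlation. Of 18 multipotent progenitor genes 16 fell and none rose (17 and 0 adjusted over the list alone; median -1.29). They included Cd34, the sialomucin of early progenitors (10.7 ± 3.40 against 67.8 ± 3.36), and Cd27, a TNF receptor family member (log2 fold change -2.14, SE 0.17). Of 23 quiescence genes 15 fell, the same number adjusted over the list alone, among them Cited2 (-1.62, SE 0.11) and Egr1 (-2.17, SE 0.18), which restrains stem cell cycling. Of 22 erythroid genes 11 rose and 2 fell (13 and 2 adjusted over the list alone; median 0.52), including the biliverdin reductase gene Blvrb (1483 ± 99.9 against 715 ± 47.5) and the erythropoietin receptor gene Epor (log2 fold change 0.99, SE 0.13). Of 40 interferon response genes 27 fell and none rose, also adjusted over the list alone (median -0.80), including Xaf1 (-2.36, SE 0.19) and Oasl2 (-2.14, SE 0.24).

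Markers of other blood lineages and several housekeeping programmes moved in the same comparison, in lists that passed camera but not with an estimated correlation. Of 4 genes of the sort gate 3 fell, also adjusted over the list alone (adjusted p = 0.0699 with an estimated correlation): Ly6a, which encodes Sca-1, went from 152 ± 50.1 to 21.9 ± 2.94 and Flt3 from 15.5 ± 3.15 to 3.93 ± 0.0873, while Kit stood at 28.8 ± 2.46 in WT Reserve and 29.5 ± 1.16 in KO Reserve. The list takes no account of whether a gate keeps or removes cells with a marker, so a joint fall has no single meaning for the sort. Granulocyte and monocyte markers fell for 19 of 25 genes (20 adjusted over the list alone; adjusted p = 0.0824 with an estimated correlation), with lysozyme gene Lyz2 at 493 ± 120 and 110 ± 22.7. Macrophage and dendritic cell markers fell for 11 of 16 genes (12 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation), with the invariant chain gene Cd74 at 227 ± 15.6 and 18.5 ± 5.25. Megakaryocyte markers fell for 12 of 21 genes (14 adjusted over the list alone; adjusted p = 0.349 with an estimated correlation), including the transcription factor gene Nfe2 (log2 fold change -1.39, SE 0.09). Genes for ribosomal proteins rose for 74 of 78 (75 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation), and nuclear genes of oxidative phosphorylation rose for 60 of 75 (61 adjusted over the list alone; adjusted p = 0.0691 with an estimated correlation). Examples are Rps2 (1.06, SE 0.09) and the cytochrome oxidase subunit gene Cox7c (0.94, SE 0.10). Glycolysis genes fell for 16 of 26 (17 adjusted over the list alone; adjusted p = 0.165 with an estimated correlation), including the glucose transporter gene Slc2a1 (-1.77, SE 0.12) and the pyruvate kinase gene Pkm (-1.93, SE 0.17). Immediate early genes fell for 17 of 26, also adjusted over the list alone (adjusted p = 0.0699 with an estimated correlation), including Fos (-2.50, SE 0.21). Of 8 Hoxa genes 6 fell, also adjusted over the list alone (adjusted p = 0.243 with an estimated correlation), led by Hoxa9 (-2.08, SE 0.20). The 28 p53 targets did not pass (adjusted p = 0.838), and their median of -0.14 turned to 0.10 with quantile normalization.

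KO Ctrl against WT compares the genotypes outside the reserve set. Mpo and Ctsg, genes of myeloid granule enzymes, were nearly silent in the knockout, while of 25 granulocyte and monocyte markers 3 fell and 1 rose (3 and 2 adjusted over the list alone; median -0.12, adjusted p = 0.315 with an estimated correlation). Mpo, which encodes myeloperoxidase (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413), fell from 60.0 ± 5.91 to 0.098 ± 0.152 (log2 fold change -5.80, SE 0.28, adjusted p = 3.4e-09). The libraries are unstranded and the antisense gene Gm11505 overlaps Mpo, with 28.0 ± 2.25 in WT and 0.0503 ± 0.0872 in KO Ctrl. Ctsg, which encodes cathepsin G (ENSMUSG00000040314, chromosome 14, 56099881 to 56102574), was at 25.5 ± 1.81 in WT and listed at 0 in all 3 KO Ctrl libraries. Mcpt8, a basophil granule protease gene, fell from 7.47 ± 0.687 to 0.188 ± 0.326 (adjusted p = 0.000117), and Tyrobp, an adaptor of myeloid and natural killer cell receptors, from 12.1 ± 1.60 to 2.30 ± 1.02. Ctse, which encodes cathepsin E, rose from 1.14 ± 0.295 to 19.4 ± 4.40 (log2 fold change 3.24, SE 0.20).

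In this comparison 218 genes rose and 160 fell. The share of changed genes that were higher, 57.7%, became 37.5% with median-ratio scaling. The total of 378 moved by more than 1.5 times without WT replicate 1 (197), WT replicate 2 (223), WT replicate 3 (132), KO Ctrl replicate 2 (166) or KO Ctrl replicate 3 (230), and library weights gave 1480. Of the 17 lists past camera, p53 targets and mast cell, basophil and eosinophil markers held with an estimated correlation. Of 28 p53 targets 9 fell and none rose (13 and 0 adjusted over the list alone; median -0.44, adjusted p = 0.0135 with an estimated correlation), among them Phlda3, an inhibitor of Akt (57.8 ± 5.80 in WT, 25.9 ± 5.31 in KO Ctrl). Of 12 mast cell, basophil and eosinophil markers 3 fell (5 adjusted over the list alone; median -0.74, adjusted p = 0.0221 with an estimated correlation). Mitotic genes rose for 17 of 49 (35 adjusted over the list alone, with 1 lower; adjusted p = 0.0656 with an estimated correlation), including topoisomerase gene Top2a (log2 fold change 0.60, SE 0.09) and the kinesin genes Kif11 (0.68, SE 0.12) and Kif23 (0.75, SE 0.12). B lymphoid genes rose for 7 of 20 (11 adjusted over the list alone; adjusted p = 0.0652 with an estimated correlation), including the surrogate light chain gene Igll1 (10.04 ± 1.55 and 29.6 ± 4.64) and Cd24a (0.95, SE 0.13). Glycolysis genes fell for 6 of 26 and rose for 1 (9 and 2 adjusted over the list alone; adjusted p = 0.154 with an estimated correlation), with the phosphoglycerate mutase gene Pgam1 at -0.64 (SE 0.09). Megakaryocyte markers had a median of -0.42, with 2 of 21 lower (4 adjusted over the list alone; adjusted p = 0.299 with an estimated correlation). The noncanonical Wnt list had a median of 0.18 (0.11 with quantile normalization and 0.05 with the length trend removed), with 2 of 28 higher (5 adjusted over the list alone; adjusted p = 0.315 with an estimated correlation), including the planar polarity gene Vangl1 (1.20, SE 0.15). LT-HSC genes did not pass (1 of 38 higher, median 0.01, adjusted p = 0.411).

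Wnt5a against WT asks what the Wnt5a label changed in wild-type cells. Basophil protease genes rose: Prss34, a basophil serine protease gene (ENSMUSG00000056399, chromosome 17, 25298394 to 25300165), was at 36.0 ± 17.6 in Wnt5a against 0.008 ± 0.0139 in WT (log2 fold change 5.08, SE 0.24, adjusted p = 3.14e-09). Mcpt8 rose from 7.47 ± 0.687 to 58.4 ± 20.4 (2.76, SE 0.32, adjusted p = 0.00131), a call that ended with a pseudocount of 0.1 (2.89, adjusted p = 0.191). The p53 targets, such as Cdkn1a, which encodes the cell cycle inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), had lower values as a list. Cdkn1a stood at 211 ± 20.2 in WT and 111 ± 44.6 in Wnt5a (-0.99, SE 0.21, adjusted p = 0.217).

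Past the threshold over all genes, limma called 6 genes higher and 1 lower, with 1126 at an unadjusted p below 0.05. The other 5 genes, named here after their values were seen, were Clec12a (0.802 ± 0.172 and 3.05 ± 0.578 in WT and Wnt5a), Tcrg-C4 (1.15 ± 0.330 and 3.47 ± 0.920), Cd28 (3.63 ± 0.721 and 0.983 ± 0.538), and the immunoglobulin segments Ighv10-3 (1.60, 1.14 and 2.23 in the Wnt5a libraries) and Ighv1-18 (1.31, 7.81 and 4.43), both listed at 0 in WT. The total was 4 without WT replicate 1, WT replicate 3 or Wnt5a replicate 1, 3 without WT replicate 2 or Wnt5a replicate 2, and 16 without Wnt5a replicate 3, and library weights gave 1541. Of 11 lists past camera, p53 targets held with an estimated correlation (median -0.37, adjusted p = 0.0105 with an estimated correlation); limma called 0 of the 28 over all genes, with 14 lower and 1 higher at an unadjusted p below 0.05 and 13 lower adjusted over the list alone. Megakaryocyte markers moved with them (median -0.35, adjusted p = 0.348 with an estimated correlation), with 0 of 21 called by limma, and 4 lower and 1 higher at an unadjusted p below 0.05. Mitotic genes had a median of 0.32, with 0 of 49 called by limma over all genes, 28 higher at an unadjusted p below 0.05 and 17 higher adjusted over the list alone (adjusted p = 0.13 with an estimated correlation). Mast cell, basophil and eosinophil markers rose for 2 of 12 (6 higher and 1 lower adjusted over the list alone; median 0.49, adjusted p = 0.0766 with an estimated correlation).

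**Figure D2:**
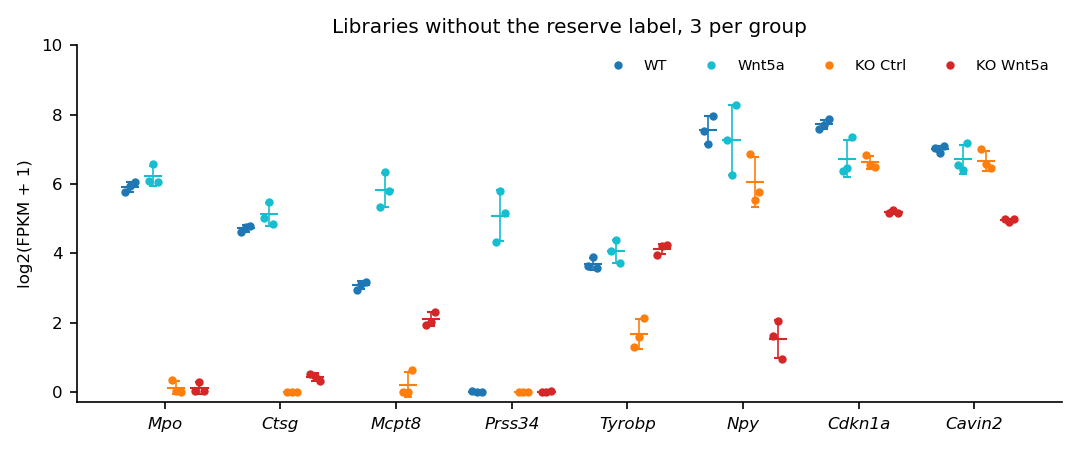
Expression of 8 genes in the 12 libraries without the reserve label, as log2(FPKM + 1) on the vertical axis; each point is 1 library, horizontal lines are group means and bars are SD over 3 libraries. Mpo and Ctsg lie near 0 in both knockout groups, Prss34 is high in the Wnt5a group alone among these 4 groups, and Cdkn1a and Cavin2 are lowest in KO Wnt5a.

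KO Wnt5a against KO Ctrl asks what the Wnt5a label changed in knockout cells. Npy, which encodes neuropeptide Y, fell from 71.8 ± 38.7 to 2.05 ± 1.10 (log2 fold change -4.52, SE 0.45, adjusted p = 0.000202). Tyrobp, low in KO Ctrl, rose from 2.30 ± 1.02 to 16.6 ± 1.84 (2.45, SE 0.20, adjusted p = 3.7e-06), beside 12.1 ± 1.60 in WT. Mcpt8 rose to 3.31 ± 0.606 from 0.188 ± 0.326 (1.88, SE 0.32). Mpo and Ctsg remained low, at 0.089 ± 0.126 and 0.358 ± 0.103. Cdkn1a fell from 98.6 ± 12.9 to 35.5 ± 1.49 (-1.44, SE 0.21, adjusted p = 0.00193), and Cavin2, a caveolar coat gene of platelets, from 103 ± 21.6 to 30.1 ± 0.866 (-1.72, SE 0.20).

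Here 45 genes rose and 101 fell. The total was 65 without KO Wnt5a replicate 3, 69 without KO Ctrl replicate 1 and 81 without KO Wnt5a replicate 2. Among the largest changes were the ribosomal protein-like gene Rpl39l (3.14, SE 0.24) and the immunoglobulin segment Ighv5-9-1 (27.8, 13.7 and 14.4 in KO Wnt5a, listed at 0 in KO Ctrl) on the higher side, and the heparan sulfate proteoglycan gene Gpc4 (-2.50, SE 0.26), the VEGF receptor gene Flt1 (-2.39, SE 0.30) and the tubulin gene Tubb6 (-2.15, SE 0.26) on the lower side. Of 6 lists past camera, p53 targets held with an estimated correlation: 3 of 28 fell (6 adjusted over the list alone; median -0.29, adjusted p = 0.0441 with an estimated correlation), including Phlda3 (25.9 ± 5.31 and 9.94 ± 1.74). Megakaryocyte markers fell for 6 of 21 (13 adjusted over the list alone; median -0.99, adjusted p = 0.119 with an estimated correlation). Mast cell, basophil and eosinophil markers rose for 4 of 12, also adjusted over the list alone (median 0.52, adjusted p = 0.119 with an estimated correlation). Transcripts encoded in mitochondria had a median of -0.39; limma called 0 of 14 over all genes, with 8 lower at an unadjusted p below 0.05 and 7 adjusted over the list alone (adjusted p = 0.233 with an estimated correlation).

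Whether the Wnt5a label brought knockout cells back toward wild type was examined for the 378 genes changed in KO Ctrl. Of these, 25 also changed from KO Ctrl to KO Wnt5a: 19 in the opposite direction, among them Tyrobp and Mcpt8, and 6 in the same direction, among them Phlda3 and Syce1. Counted without regard to shared libraries, the 19 were 8 genes higher then lower (1.5 expected from n1 × n2 / N) and 11 lower then higher (0.5 expected), and the 6 were 1 higher in both (0.7 expected) and 5 lower in both (1.1 expected). Both comparisons use the KO Ctrl libraries, so part or all of the excess of opposite changes can come from them. Across all tested genes r was -0.342 where simulated noise without effects gave -0.498, with covariances of -0.0772 and -0.0896. Of all 378 genes, 201 (53.2%) had the opposite sign from KO Ctrl to KO Wnt5a. Simulated noise gave 66.6%, but over all tested genes and not over called ones, so the 2 shares are not comparable. Of the 378 genes, 303 also differed from WT in KO Wnt5a in the same direction and 74 were not called there, including 18 of the 19.

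KO Wnt5a against WT shows what still differed. Of 28 p53 targets 17 fell and 1 rose (21 and 3 adjusted over the list alone; median -0.81). Of 16 lists past camera, this list alone held (adjusted p = 0.00229 with an estimated correlation). Cdkn1a stood at 211 ± 20.2 in WT and 35.5 ± 1.49 in KO Wnt5a (log2 fold change -2.53, SE 0.21, adjusted p = 2.69e-06), Phlda3 at 57.8 ± 5.80 and 9.94 ± 1.74, and the cyclin G1 gene Ccng1 at 142 ± 14.4 and 50.03 ± 5.13. Megakaryocyte markers fell for 17 of 21 (19 adjusted over the list alone; median -1.54, adjusted p = 0.114 with an estimated correlation), including Cavin2 (-2.06, SE 0.20) and the platelet glycoprotein gene Gp9 (-1.38, SE 0.16). Mitotic genes rose for 28 of 49 and fell for 1 (38 and 2 adjusted over the list alone; median 0.49, adjusted p = 0.224 with an estimated correlation), including Mki67 (0.83, SE 0.12), which encodes the proliferation marker Ki-67. B lymphoid genes rose for 7 of 20 (11 adjusted over the list alone; adjusted p = 0.257 with an estimated correlation). Mpo (-5.81, SE 0.28) and Npy (-6.02, SE 0.45) fell, and Syce1, a gene of the meiotic synaptonemal complex, rose (4.46, SE 0.29). Hoxb2 was called higher (0.63, SE 0.19, adjusted p = 0.0412), a call that ended with quantile normalization (0.46, adjusted p = 0.145), median-ratio scaling (0.52, adjusted p = 0.0959), no filter (adjusted p = 0.0889) or a pseudocount of 0.1 (adjusted p = 0.0928), and without any 1 of the 6 libraries (0.59 to 0.70 with adjusted p from 0.0604 to 0.14: WT replicate 1, 2 or 3, or KO Wnt5a replicate 1, 2 or 3).

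In total 972 genes rose and 719 fell against WT. With quantile normalization 573 were higher and 854 lower, and 690 genes passed in all without WT replicate 3, 1046 without WT replicate 1, and 1087, 1094 and 1064 without KO Wnt5a replicate 1, 2 and 3, while library weights gave 3697.

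**Figure D3:**
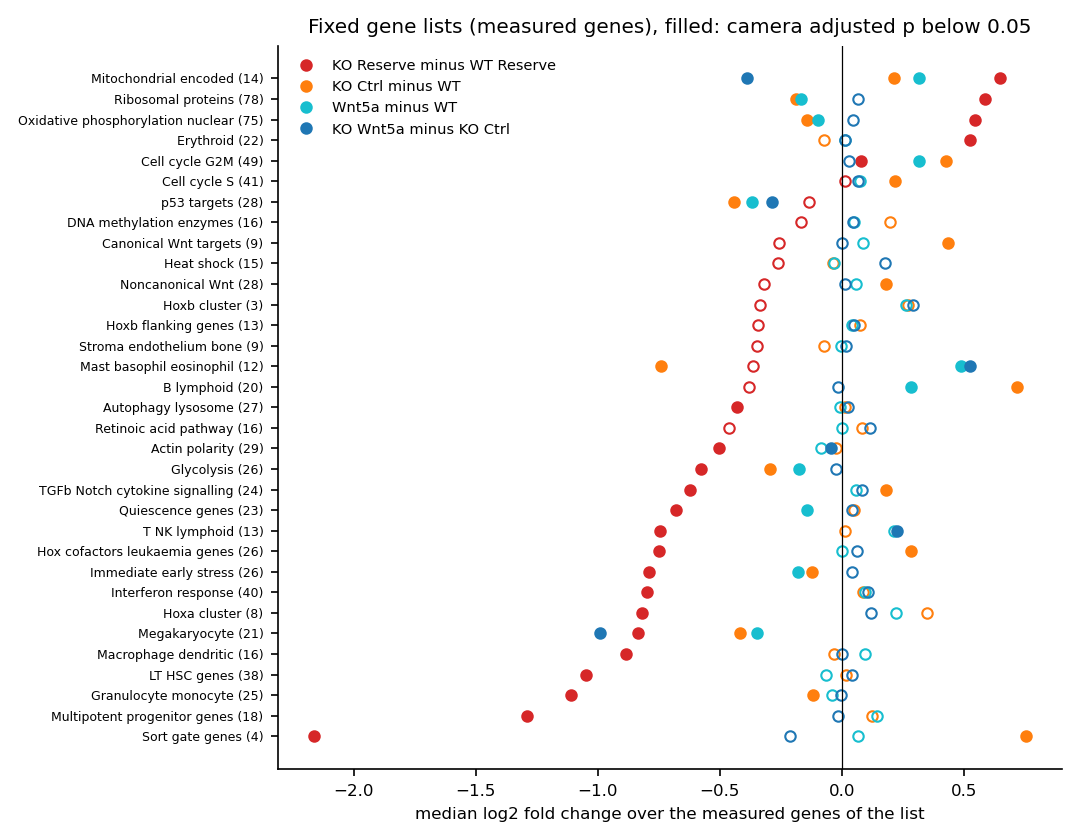
Median log2 fold change (horizontal axis) of the measured genes of each of 33 gene lists (vertical axis, number of measured genes in brackets) in 4 comparisons; filled symbols mark lists with a camera adjusted p below 0.05 at the preset correlation. The spread of medians is widest for KO Reserve against WT Reserve, from -2.16 for the sort gate genes to 0.65 for transcripts encoded in mitochondria, whose call was not kept with an estimated correlation (adjusted p = 0.243).

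The difference between the 2 Wnt5a effects, in knockout and in wild-type cells, was tested as an interaction. It was called for 10 genes: the Wnt5a effect was lower in the knockout for 7, including Prss34 (log2 difference -5.07, SE 0.34) and Npy (-4.23, SE 0.63), and higher for 3, including Tyrobp (2.09, SE 0.28). When genes needed a mean of at least 5 FPKM the call ended for Prss34 (adjusted p = 0.101) and Npy (0.062), and that of Npy also ended with only the groups of the contrast fitted (0.181) and without KO Wnt5a replicate 1 (0.0619) or 3 (0.0559), WT replicate 1 (0.0608) or 2 (0.0806) or Wnt5a replicate 1 (0.0589). The total was 22 without Wnt5a replicate 2 and 18 without KO Ctrl replicate 3. Of 8 lists past camera none held with an estimated correlation. Limma called 0 of the 28 p53 targets, with 0 at an unadjusted p below 0.05 (median 0.04, adjusted p = 0.868).

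The difference between the 2 knockout effects, in the reserve set and outside it, was called for 4415 genes, with 1147 higher and 3268 lower in the reserve set, around a median of all genes of -0.22. With quantile normalization the split was 2155 and 1969. LT-HSC genes were lower in the reserve comparison for 28 of 38 and higher for 2 (30 and 3 adjusted over the list alone; median -1.01, adjusted p = 0.022 with an estimated correlation). Interferon response genes were lower for 26 of 40 and higher for 1 (27 and 1 adjusted over the list alone; median -1.04, adjusted p = 0.022 with an estimated correlation). Mpo (5.61, SE 0.39) differed in the other direction, since it stood at 131 ± 48.2 in WT Reserve and 118 ± 52.7 in KO Reserve. These were among 17 lists past camera, 8 of which held with an estimated correlation.

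WT Reserve against WT compares the reserve label within wild-type cells. No label names a batch for either set. The deposited column names of the reserve libraries alone carry the letters fl, whose meaning is not stated. A difference that these letters mark could not be told from the reserve label. Platelet genes were higher in WT: Pf4, which encodes platelet factor 4, was at 22930 ± 4775 in WT and 110 ± 3.31 in WT Reserve (log2 fold change -7.67, SE 0.32), and the integrin gene Itga2b at 478 ± 54.8 and 14.1 ± 1.22. All 21 megakaryocyte markers fell, also adjusted over the list alone (median -4.16, adjusted p = 0.0682 with an estimated correlation). Genes of other blood lineages were abundant in WT Reserve. Car1, the carbonic anhydrase gene of red cell precursors, was at 3370 ± 459 and listed at 0 in all 3 WT libraries, S100a8, a calprotectin subunit gene of granulocytes, was at 2603 ± 1172 against 0.051 ± 0.0883, and Dntt, the terminal transferase gene of lymphoid precursors, at 246 ± 30.3 against 0.654 ± 0.607. Erythroid genes rose for 19 of 22 and fell for 1, granulocyte and monocyte genes rose for 23 of 25 and fell for 1, and B lymphoid genes rose for 19 of 20, each also adjusted over the list alone. With an estimated correlation their adjusted p was 0.00184, 0.0137 and 0.0137. Multipotent progenitor genes had a median of 2.49, with 14 of 18 higher and 3 lower at an unadjusted p below 0.05 in limma. The p53 targets fell for 21 of 28 and rose for 2 (22 and 2 adjusted over the list alone; median -1.26, adjusted p = 0.0204 with an estimated correlation). In all 4400 genes rose and 3990 fell, and 12 lists passed camera, 6 of them with an estimated correlation.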

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

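The other splits of the libraries were planned, whereas the tests of scaling, cell types, megakaryocyte transcripts, animal sex, flanking DNA and shared libraries were chosen only after the results were seen. The genes and lists given with a log2 difference were singled out because an effect differed between groups by an interaction test in limma, and the 3 patterns weighed after them come from comparisons of pairs of groups.

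The Wnt5a effect differed between genotypes for 10 genes, given as log2 differences, knockout minus wild type. It was higher in the knockout for Tyrobp (2.09), Rpl39l (3.20) and the immunoglobulin segment Ighv5-9-1 (4.14). It was lower for Prss34 (-5.07), Npy (-4.23), 3830403N18Rik (-2.49), Fam169a (-2.16), Gm128 (-2.21), the immunoglobulin segment Ighv1-26 (-2.52) and the phosphatase gene Ppef2 (-2.35); 3830403N18Rik, Gm128, Ighv1-26 and Ppef2 were named after their values were seen. Values of the immunoglobulin segments depend on the pseudocount, and the call of Rpl39l ended with a pseudocount of 0.1 (5.90, adjusted p = 0.0745). The call of Prss34 ended with a mean of at least 5 FPKM (adjusted p = 0.101), and that of Npy with that filter (0.062), with only the groups of the contrast or the 12 libraries fitted (0.181), and without KO Wnt5a replicate 1 (adjusted p = 0.0619) or 3 (0.0559), WT replicate 1 (0.0608) or 2 (0.0806), or Wnt5a replicate 1 (0.0589). That of Fam169a ended with quantile normalization (-1.97, adjusted p = 0.0805), with no filter (0.076), with only the groups of the contrast or the 12 libraries fitted (0.141), and without KO Wnt5a replicate 2 (adjusted p = 0.0705) or 3 (0.0559), WT replicate 1 (0.0526) or 2 (0.0948), or Wnt5a replicate 1 (0.0589) or 3 (0.0555). The count was 22 without Wnt5a replicate 2 and 18 without KO Ctrl replicate 3. Of 100 splits within the pairs of groups, the real one included, 6 gave at least 10 genes and the highest other gave 153, so chance is not excluded for this count. The highest exchanged KO Wnt5a with KO Ctrl. All 5 other splits with at least 10 genes kept the libraries of at least 1 pair of groups together, and of 81 splits that mixed both pairs the highest gave 4. Among lists, the median log2 difference was -0.39 for sort gate genes, -0.27 for mitotic genes, -0.55 for megakaryocyte markers, -0.30 for B lymphoid genes, 0.06 for heat shock genes, 0.15 for nuclear oxidative phosphorylation genes, -0.63 for transcripts encoded in mitochondria and 0.22 for ribosomal protein genes. None of these 8 lists held with an estimated correlation (adjusted p from 0.284 to 0.623).

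The knockout effect differed between the reserve set and the other libraries for 4415 genes. The highest of the other 99 splits gave 3673 (1 of 100 splits, the real one, was as high). The split with 3673 exchanged the genotype labels of the reserve set and kept the others, so 3673 is also the count if those labels were exchanged. Of 81 splits that mixed both pairs the highest gave 8. These splits cannot exclude chance. A split that mixes groups adds their differences to the spread within groups, and a split that keeps a pair together keeps its real difference. The knockout effect on stem and progenitor genes was lower in the reserve set: Procr (-3.17), Ndn (-3.04), Hlf (-2.81), Meis1 (-1.82), Cd34 (-2.76), Cd27 (-3.05), Cited2 (-1.54), Egr1 (-2.64), Ly6a (-3.70), Flt3 (-2.37), Hoxa9 (-2.94), Hoxb5os (-1.33) and Kit (-0.83). Kit did not fall in KO Reserve, and its difference came from higher values in KO Ctrl than in WT (log2 fold change 0.86). The limma call of that rise ended with only the groups of the comparison fitted (adjusted p = 0.0833) and without WT replicate 3 (0.119), among other settings. The interaction call of Kit ended without KO Ctrl replicate 2 (adjusted p = 0.0595) or 3 (0.0524), WT replicate 3 (0.0654) or WT Reserve replicate 1 (0.0503), and with quantile normalization (-0.54, adjusted p = 0.117), median-ratio scaling (0.131), no filter (0.0586) or the length trend removed (0.0978). Genes of the interferon response and of stress, Xaf1 (-3.73), Oasl2 (-3.07) and Fos (-1.91), and Slc2a1 (-1.50), Pkm (-1.66) and Pgam1 (-0.48) differed the same way, while the glycolysis list did not pass (9 of 26 lower, also adjusted over the list alone; median -0.21, adjusted p = 0.114) and its median turned to 0.06 with median-ratio scaling and 0.10 with the length trend removed. So did lineage genes: Lyz2 (-2.03), Cd74 (-2.23), Nfe2 (-1.30), Gp9 (-0.68), Igll1 (-1.86), Cd24a (-1.01), Dntt (-1.29), Clec12a (-0.92), Tcrg-C4 (-3.34), S100a8 (-2.33) and Ctse (-3.29). The same holds for Kif11 (-0.62), Kif23 (-1.21), Tubb6 (-1.44), Syce1 (-2.96) and Klk1b22 (-2.27), and for Tcrg-C1 (-2.90), Rxrg (-2.17), Socs2 (-2.32) and Emcn (-3.03). The difference was upward for the erythroid genes Ank1 (1.62), Blvrb (1.19), Epor (0.93) and Car1 (0.59), the granule enzyme genes Mpo (5.61), Ctsg (4.96) and Mcpt8 (2.40), and Rps2 (1.30), Cox7c (1.05), Phlda3 (1.36), Ccng1 (0.72) and Gpc4 (1.49). It was also upward for AA465934 (11.28), Xist (1.95) and, both chosen after their values were seen, Gm11505 (2.91) and Eif5al3-ps (14.00).

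Of 17 gene lists that differed in the same test, 8 held with an estimated correlation. These had median log2 differences of -1.01 (LT-HSC genes), -2.57 (sort gate genes), -1.54 (multipotent progenitor genes), 0.58 (erythroid genes), -1.04 (interferon response genes), -1.13 (Hox cofactor and leukaemia genes), 0.65 (nuclear oxidative phosphorylation genes) and -0.67 (TGF-beta, Notch and cytokine signalling genes). The other 9, with adjusted p from 0.0901 to 0.482 with an estimated correlation, had medians of -1.17 (Hoxa genes), -0.75 (quiescence genes), -0.90 (macrophage and dendritic cell markers), -1.01 (B lymphoid genes), -0.72 (immediate early genes), 0.29 (p53 targets), 0.52 (transcripts encoded in mitochondria), 0.76 (ribosomal protein genes) and -0.56 (actin and polarity genes). Medians that moved by over 1.5 times under quantile normalization, median-ratio scaling or removal of the length trend were those of oxidative phosphorylation (0.40 to 0.98), TGF-beta, Notch and cytokine signalling (-0.40 to -0.36), quiescence (-0.46 to -0.41), immediate early (-0.50 to -0.43), macrophage and dendritic cell (-0.66 to -0.60), p53 target (0.53 to 0.59), ribosomal protein (0.42 to 1.10) and actin and polarity genes (-0.49 to -0.26) and of transcripts encoded in mitochondria (0.31 to 0.81).

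LT-HSC genes were lower in KO Reserve than in WT Reserve. Scaling of the libraries is argued against, since the list's median stayed at -0.83 (SE 0.23) under quantile normalization. A lower share of the main cell type stays open. Erythroid and granulocyte and monocyte markers moved apart by 1.70 (SE 0.24) on the same scale, but 1 other cell type can grow while another shrinks. Growth in the number of erythroid cells stays open with it. Another sex makeup of the animals cannot be told apart from the genotype in these 6 libraries, with Xist differing by 2.66 (SE 0.25). The knockout of DERARE in the animals stays open as a biological explanation, as do exchanged genotype labels, strain background and any difference of handling between the groups.

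Mpo and Ctsg were near 0 in KO Ctrl and KO Wnt5a and not in WT and Wnt5a. Mature granulocytes in WT and Wnt5a are argued against, since 5 of their abundant transcripts (S100a8, S100a9, Ltf, Ngp and Camp) summed to 1.94 ± 1.33 FPKM in WT and 3.22 ± 1.03 in Wnt5a, below every KO Ctrl library (9.06 ± 2.45). For monocytes, Lyz2 (139 in WT, 127 in KO Ctrl), Ctss, Ccr2 and Ly6c2 had a median log2 fold change of 0.14 (SE 0.27) in KO Ctrl against WT. This does not decide on monocytes, since Ctss (1.745), Ccr2 (0.568) and Ly6c2 (0.405) were too low in WT for a large fall to show. Basophil or mast cell lineage cells, mature forms of which a stem cell sort would remove, stay open as a candidate source for KO Ctrl, where that list had a median of -0.74 (SE 0.27) against WT, but are argued against for KO Wnt5a, where the median was -0.08 (SE 0.28) and Mpo stayed at 0.089 FPKM. DNA flanking the Hoxb cluster on chromosome 11 is argued against as a local effect for Ctsg, which lies on chromosome 14, and cannot be told apart for Mpo, with an odds ratio of 1.5 for changed genes within 20 Mb of Hoxb4 (Fisher's exact test, two-sided p = 0.11) beside 3 of 11 genes that fell over 4-fold, Mpo and the overlapping Gm11505 left out, where 0.38 were expected (p = 0.00545 by the same exact test). AA465934, which had higher values in KO Reserve than in WT Reserve, is among those 3 genes. In the reserve set the knockout effect was higher by 5.61 on the log2 scale for Mpo and 4.96 for Ctsg (limma interaction, adjusted p = 3.01e-07 and 0.000132). Mpo was not near 0 in either reserve group, which argues against its silencing in every cell that carries the knockout allele. Early myeloid progenitors and an effect of the knockout limited to the libraries without the reserve label were not tested and stay open.

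The p53 targets were lower from WT to KO Wnt5a, with both the knockout and the Wnt5a label on the way. The shared WT libraries are argued against as the whole source, since KO Wnt5a against Wnt5a, which uses none of them, gave a median of -0.39 (SE 0.12), with 6 of 28 lower and 1 higher and adjusted p = 0.0184 with an estimated correlation. Scaling of the libraries is argued against by the median of -0.90 (SE 0.15) under quantile normalization. Fewer megakaryocyte lineage transcripts stay open as a candidate explanation, since those markers fell further in the same comparison (17 of 21 lower, median -1.54, SE 0.27; adjusted p = 0.114 with an estimated correlation) and also had lower medians in KO Ctrl (-0.42), Wnt5a (-0.35) and WT Reserve (-4.16) against WT. The 2 lists did not always move together. In KO Reserve against WT Reserve the markers had a median of -0.83 and the p53 targets -0.14, or 0.10 with quantile normalization. In the Wnt5a interaction the markers had -0.55 and the p53 targets 0.04. Differences in stress during handling were not tested and stay open beside an effect of the knockout and of Wnt5a.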

How the results depend on the processing

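Tests on the 12 libraries without the reserve label, on coding genes of at least 300 bp and with the length trend removed were chosen after the data were seen; the other settings were planned. Of 14517 values of named genes under other settings, 13684 kept their side of the threshold, 602 lost the call and 231 gained it. With a call in either setting, 0 turned direction. Values without a call in both settings were counted as kept even where their direction turned. Of 241 counts and medians outside the left-out libraries, 206 were kept, 2 gained a call and 33 moved. Counts were kept when within 1.5 times of the main value. Hoxb medians were kept when their call stayed the same, whatever their size. The cause was not tested except where the setting itself tests fewer genes, uses fewer libraries or asks for more.

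Quantile normalization gave 4 genes for Wnt5a against WT and 10 lists for KO Wnt5a against WT, and median-ratio scaling 3 genes for Wnt5a against WT. Without a filter 231 genes changed in KO Ctrl, 77 (with 10 lists) in KO Wnt5a against KO Ctrl and 16 in the interaction of Wnt5a with genotype, and the Hoxb medians were 0.24 (adjusted p = 0.0162) in KO Ctrl and 0.18 (adjusted p = 0.0151) in KO Wnt5a against KO Ctrl. A mean of at least 5 FPKM left 4 genes for Wnt5a against WT, 67 for KO Wnt5a against KO Ctrl and 1 for the Wnt5a interaction. With only the groups of a comparison, 3720 genes changed in KO Reserve, 72 in KO Wnt5a against KO Ctrl and 2555 in KO Wnt5a against WT, and with only the 12 libraries 769 changed in KO Ctrl. Limma without trend or robust moderation gave 4 genes for Wnt5a against WT. Library weights gave 1541 for Wnt5a against WT, 1480 for KO Ctrl, 3697 for KO Wnt5a against WT and 54 for the Wnt5a interaction, and coding genes of at least 300 bp gave 16 for the last. A minimum log2 change of 1 left 1586 genes for KO Reserve, 102 for KO Ctrl, 332 for KO Wnt5a against WT, 3572 for WT Reserve against WT and 2012 for the interaction of genotype with reserve. With an estimated correlation 5 lists held for KO Reserve, 2 for KO Ctrl, 1 for Wnt5a against WT, 1 for KO Wnt5a against KO Ctrl, 1 for KO Wnt5a against WT, 6 for WT Reserve against WT, 8 for the reserve interaction and 0 for the Wnt5a interaction, where camera at the preset correlation called 8.

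Leaving out each library in turn gave 4649 to 5998 genes for KO Reserve, 132 (without WT replicate 3) to 461 for KO Ctrl, 3 to 16 (without Wnt5a replicate 3) for Wnt5a against WT, 65 (without KO Wnt5a replicate 3) to 156 for KO Wnt5a against KO Ctrl and 690 (without WT replicate 3) to 1158 for KO Wnt5a against WT. The ranges were 7563 to 8040 for WT Reserve against WT, 7 to 22 (without Wnt5a replicate 2) for the Wnt5a interaction and 3616 to 4922 for the reserve interaction. Lists past camera ranged over 19 to 22, 15 to 17, 10 to 14, 5 to 9, 14 to 17, 12 to 13, 6 to 8 and 16 to 18 in that order. Hoxb medians ranged from -0.50 to -0.19 in KO Reserve, 0.16 to 0.55 in KO Ctrl, 0.14 to 0.44 in Wnt5a and 0.01 to 0.47 in KO Wnt5a against KO Ctrl. Replicate number as a block gave 5847, 394, 8, 137, 1619, 8375, 13 and 4389 genes in the same order, and none of 45 correlations between libraries of equal number exceeded 0.1 (-0.0917 to 0.1), so the numbers show no pairing. Fold changes were related to transcript length with Spearman's rho across genes of -0.20 in WT Reserve against WT, 0.14 in KO Ctrl, 0.14 in KO Wnt5a against WT, 0.09 in Wnt5a against WT, 0.02 in KO Wnt5a against KO Ctrl, -0.04 in KO Reserve, -0.05 in the Wnt5a interaction and -0.09 in the reserve interaction. Depth puts 3 fragments on a transcript of 1 kb at 0.075 to 0.152 FPKM, so differences between values below this are not detectable.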

Other observations

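The tests of chromosomal clustering, of repetition between the sets and of exchanged labels were chosen only after the values were seen, while the splits of the libraries were planned. Tcrg-C1, which encodes a constant region of the T cell receptor gamma chain and was named for WT Reserve against WT, was at 240 ± 26.3 FPKM (SD, n = 3) in WT Reserve, 51.5 ± 20.8 in KO Reserve (log2 fold change -2.26, SE 0.21, adjusted p = 6.11e-07) and 0.0957 ± 0.0547 in WT. The joining segment Trgj1, a very short feature, stood at 20950 ± 4724 and 3544 ± 1367 in the reserve groups (adjusted p = 0.224) and was listed at 0 in WT, Wnt5a and KO Ctrl.

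Genes that handle retinoic acid were also among those lower in KO Reserve, although their list did not pass: of 16 measured genes 7 fell and 2 rose (8 and 2 adjusted over the list alone; median -0.46, adjusted p = 0.368). That median was -0.25 with quantile normalization and -0.27 with the length trend removed, where 5 were lower and 3 higher. Rxrg, which encodes a retinoid X receptor, went from 8.74 ± 2.73 to 1.42 ± 1.03 (log2 fold change -2.06, SE 0.26). Of 24 genes of TGF-beta, Notch and cytokine signalling 14 fell and none rose (15 and 0 adjusted over the list alone; median -0.62, or -0.40 with quantile normalization; adjusted p = 0.0699 with an estimated correlation), including Socs2, a feedback inhibitor of cytokine receptors, from 27.2 ± 5.49 to 5.46 ± 1.63. Emcn, which encodes the sialomucin endomucin, went from 10.7 ± 5.46 to 0.635 ± 0.294 (-2.73, SE 0.30), while its list of stroma, endothelium and bone markers did not pass (3 of 9 lower, also adjusted over the list alone; median -0.35, or -0.13 with quantile normalization; adjusted p = 0.239).

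Several transcripts separated the genotypes in every library, of which Eif5al3-ps and Gm11505 were chosen after their values were seen. AA465934 (chromosome 11, 83291699 to 83294632) stood at 174 ± 16.2 in WT, 160 ± 17.6 in Wnt5a, 3.29 ± 1.13 in KO Ctrl and 4.30 ± 2.21 in KO Wnt5a, but at 19.3 ± 3.15 in WT Reserve and 1208 ± 221 in KO Reserve. The pseudogene Eif5al3-ps did likewise, with 411 ± 9.21 in WT, 1.03 ± 0.365 in KO Ctrl, 3.40 ± 2.06 in WT Reserve and 323.5 ± 61.6 in KO Reserve. Klk1b22, a kallikrein gene, was listed at 0 in all 9 knockout libraries and stood at 1.12 ± 0.363 in WT, 1.496 ± 0.399 in Wnt5a and 9.52 ± 3.65 in WT Reserve. Gm11505 was lower in the knockout in both sets, at 60.5 ± 21.8 in WT Reserve and 15.4 ± 3.63 in KO Reserve. Genotype labels exchanged in 1 set could give the first pair of patterns but not the second pair. Of 33 genes called in both sets with a log2 change over 1 in each, 18 differed in direction and 15 did not (exact binomial p = 0.728), which leaves exchanged labels and a difference of strain background open.

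Sex-linked transcripts differed between groups, though Xist and the Y-linked gene Eif2s3y differed little between the groups with the Wnt5a label and their controls. In Wnt5a and KO Wnt5a, Xist was at 2.49 ± 0.344 and 4.96 ± 1.59 and Eif2s3y at 21.4 ± 2.20 and 14.5 ± 0.687. Each WT library held both Xist (2.46 to 2.76) and Eif2s3y (18.6 to 20.4). Xist was at 2.56 ± 0.171 in WT, 4.96 ± 1.47 in KO Ctrl, 0.334 ± 0.414 in WT Reserve and 7.40 ± 2.09 in KO Reserve, and the Y-linked gene Eif2s3y at 19.5 ± 0.910, 16.3 ± 5.07, 88.1 ± 11.3 and 36.8 ± 10.5 in the same order.

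The genotype effect of the reserve set was not repeated in the other libraries. Across genes, which are not independent replicates, the correlation of the 2 sets of log2 fold changes was r = -0.021. Of 213 genes called in both, 26 were higher in both (26.1 expected from n1 × n2 / N), 68 lower in both (46.9 expected), 24 higher in KO Reserve and lower in KO Ctrl (19.1 expected) and 95 the reverse (64 expected).

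Changed genes of KO Ctrl against WT were 19 of 494 genes within 20 Mb of Hoxb4 (3.85%) and 359 of 13791 elsewhere (2.60%; Fisher's exact test, two-sided p = 0.11). Clustering of all changed genes near the deleted element is neither shown nor excluded by that test. Of 13 genes that fell by more than 4-fold, 5 were within that window, which holds 3.46% of tested genes, where 0.45 were expected. Without Mpo and the overlapping Gm11505 it was 3 of 11 against 0.38 expected (Fisher's exact test, two-sided p = 0.00545), so the strongest falls may cluster there, although neighbouring genes are not independent. AA465934, which differed the other way in the reserve set, is among the 3, and the test was not repeated without it.

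Each pair of groups allows 10 splits, too few for a share under 0.05, and only 1 of the 10 gave as many genes as the real grouping each time. The real count was 5899 for KO Reserve against WT Reserve with 86 for the highest other split, 378 for KO Ctrl against WT with 0, and 7 for Wnt5a against WT with 1. It was 146 for KO Wnt5a against KO Ctrl with 4, 1691 for KO Wnt5a against WT with 2, and 8390 for WT Reserve against WT with 2.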
